A study of Mus musculus with 2 samples.

How the data were processed

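Total RNA was isolated with TRIzol from J1 mouse embryonic stem cells grown on gelatin, with Knockout Serum Replacement and 1000 U/mL LIF, after 24 h with 3 µM SB431542 or an equal volume of DMSO. Per the labels, 1 µg of total RNA went into libraries made with an Illumina TruSeq RNA kit; how small RNAs were selected, and the adapter trimming, filters and aligner, are not given in the sources used here. The deposited values are raw read counts per distinct sequence, without normalization, with the length and the sequence of each. The sequences analysed here are all of 3 to 17 nt, so longer reads, full-length miRNAs among them, are not analysed here, and the totals are of this length class only. Genome build mm9 is named in the submitters' processing notes, and no coordinate of theirs was used. Each group had 1 library, and the labels gave the group of each.

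Sequences of at least 15 nt were matched to the GENCODE M21 transcripts of the GRCm38 genome as exact, full-length matches on the sense strand. Antisense matches, made in the same way, gave the background. A matched miRNA hairpin was split at its middle, and each sequence was given to the 5p or 3p arm in which its midpoint fell, which stands here for the mature miRNA named in the plan, since coordinates of mature miRNAs were not used here. Sequences found in several miRNAs were divided equally among them. Sequences that also matched another small RNA class, or more than 5 other genes, were set aside, and those antisense to a ribosomal RNA gene annotated on the opposite strand of its locus were counted as ribosomal. The length minimum and these rules were chosen after a first assignment without them, whose ratios had been seen, and were not in the plan made before the data were examined. That first assignment is among the alternatives. Nuclear tRNA and 28S ribosomal RNA sequences were not used here, so fragments of them count as unmatched or as other classes. Those classes can include miRNA hairpins that hold the same sequence.

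The reads of each arm were scaled to 1000000 reads assigned to miRNAs (RPM), from 77907 with DMSO and 21808 with SB431542, so 3 reads correspond to 38.5 and 138 RPM. A log2 ratio was computed with a pseudocount of 0.5 read for each arm. An arm was described with at least 50 reads over both libraries. The 95% intervals of ratios are exact conditional binomial (Clopper-Pearson) intervals and those of shares are Clopper-Pearson intervals. They cover counting error only, since reads amplified without molecular identifiers are not independent molecules. No test between groups was made, because spread between libraries of a group cannot be measured with 1 library each. On data simulated at the depths of this comparison, 191 of 200 hairpin fragments returned to their own hairpin and 9 were set aside. All 20 described arms simulated with a 4-fold change were called at least 2-fold in that direction, 0 of 26 unchanged arms were, and the interval held the simulated ratio for 44 of 46. The fragments were drawn from the hairpins themselves, so their return cannot show whether other RNA is counted as miRNA. The simulated ratios held counting error only and no spread between libraries.

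The named arms were the 10 highest and 10 lowest log2 ratios among described arms with at least 10 RPM, the 10 most abundant arms, and in each of the 18 lists the 3 most abundant members and the described member with the largest ratio. Of the 63 arms this rule took, those with too few reads for a description are covered by the sums of their lists. Lists with at least 3 described arms were placed by their median among 10000 random lists of the same size matched on mean expression. The lists, the named-arm rule, the scale, the pseudocount and the 50-read minimum were set before the data were examined. Alternatives planned then were edgeR TMM factors, DESeq2 size factors, the total of all reads in the file, the miRNA total without the 5 most abundant arms, a pseudocount of 5 reads, leaving out arms that share reads, thinning the DMSO library to the depth of the other, no read minimum, a minimum of 200 reads, and shares of distinct sequences. Added after the data had been seen were minimum lengths of 14, 16 and 17 nt, no limit on other genes, keeping sequences that match another small RNA class, setting no sequence aside, a GC correction, distinct sequences with the DMSO library thinned, and the miRNA share without the 4 most abundant arms. The GC correction divided each SB431542 count by the median ratio of the sequences outside miRNA hairpins with at least 20 reads in its GC bin, 10% wide. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 for the scaling factors.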

Results

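Small RNA reads were compared between J1 mouse embryonic stem cells, a line of strain 129S4/SvJae, that had been kept for 24 h with SB431542 and the same cells kept for 24 h with its solvent, DMSO. SB431542 blocks the kinase activity of the TGF-beta, activin and Nodal type I receptors ALK4, ALK5 and ALK7, and was used at 3 µM in medium with 1000 U/mL of leukaemia inhibitory factor (LIF), which holds mouse stem cells undifferentiated. Each group had 1 library, so no difference has a replicate check, no p-value is given, and every interval covers counting error only. The reads analysed were 3 to 17 nt long, shorter than a mature miRNA, so each value describes fragments of a miRNA arm and not full-length miRNAs, which are not analysed here. The DMSO library held 1190074 such reads in 97146 distinct sequences and the SB431542 library 645925 reads in 57715 sequences, a ratio of 1.84. These totals are those of a length class and not the depth of the libraries.

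The first comparison asked how the reads of the 2 libraries were divided among RNA classes. Fragments of miRNA hairpins made up 7.87% of the 15 to 17 nt reads with DMSO (95% Clopper-Pearson interval 7.81 to 7.92; 77907 reads) and 4.21% with SB431542 (4.16 to 4.27; 21808 reads), 1.87-fold lower in the SB431542 library. Fragments of the ribosomal RNAs matched here were also lower there, at 11.1% against 13.5%. Some ribosomal RNA sequences were left out of the matching, and their fragments count as unmatched or as other classes. The direction for ribosomal RNA as a whole is therefore not known. Fragments of snoRNAs and scaRNAs, which guide RNA modification, were lower with SB431542 too, at 0.369% against 0.482%. Spliceosomal snRNA fragments stood at 0.237% with SB431542 and 0.298% with DMSO. Among distinct sequences, with the DMSO library thinned to the same number of reads, miRNA hairpins held 1.37% with DMSO and 1.18% with SB431542, ribosomal RNA 4.87% and 5.15%, and snRNAs 0.270% and 0.344%. Without thinning, which leaves the deeper DMSO library with more rare sequences, the miRNA values were 1.15% and 1.18%. Reads antisense to the hairpins, a measure of chance matches, made up 0.0342% with DMSO and 0.0228% with SB431542. They do not measure sense fragments of other RNA that hold the same sequence as a hairpin. No match to an annotated transcript was found for 70.3% of the 15 to 17 nt reads with DMSO and 74.1% with SB431542.

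**Figure D1:**
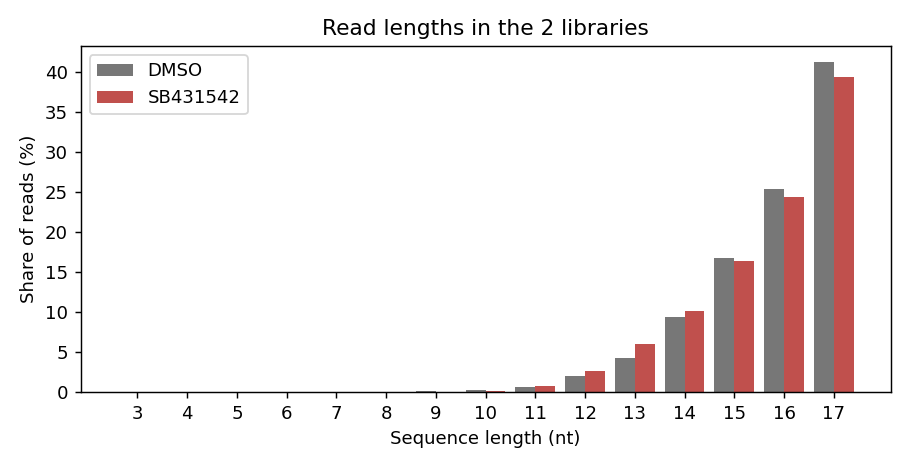
Share of all reads of each library (vertical axis, %) by sequence length (horizontal axis, nt), with grey bars for DMSO and red bars for SB431542. Sequences of 17 nt were the most frequent in both libraries, at 41.2% with DMSO and 39.3% with SB431542.

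Reads shorter than 15 nt, which were left out of the assignment, were 16.8% of the DMSO library (16.7 to 16.9) and 19.9% of the SB431542 library (19.8 to 19.97). The mean GC content of the 15 to 17 nt reads was 60.7% with DMSO and 64.2% with SB431542.

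The second comparison asked which miRNAs differ between stem cells with and without the inhibitor. A single arm, miR-293-3p of the stem-cell-specific miR-290-295 cluster, supplied 50.0% of the miRNA reads with DMSO and 47.5% with SB431542. Together with miR-25-3p, miR-382-5p and miR-409-3p it made up 83.9% and 82.3%. In reads per 1000000 miRNA reads (RPM) these arms, which supply most of the total, had ratios near 1: the log2 ratio of SB431542 to DMSO was -0.07 for miR-293-3p (-0.10 to -0.04), 0.03 for miR-25-3p (-0.03 to 0.09), 0.16 for miR-382-5p (0.09 to 0.22) and -0.09 for miR-409-3p (-0.16 to -0.02). Per reads of 15 to 17 nt the same arms were lower with SB431542, at -0.97, -0.87, -0.74 and -0.99. The sign for miR-382-5p and miR-25-3p was also negative with edgeR or DESeq2 factors, and that for miR-409-3p positive after a GC correction (0.02). The next most abundant, miR-296-3p, was lower with SB431542 (-0.34, -0.54 to -0.14). Of 43 arms with at least 50 reads over both libraries, 3 were at least 2-fold higher with SB431542, 2 were at least 2-fold lower and 38 lay between.

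The arms at least 2-fold higher in the SB431542 library were miR-5126-3p, miR-6538-5p and miR-6236-5p. The reads of miR-5126-3p numbered 183 with DMSO and 131 with SB431542, 2.56-fold higher in RPM (log2 1.36, 1.02 to 1.69). It was the only described arm whose interval lay wholly beyond 2-fold. For miR-6538-5p the reads were 235 and 155 (log2 1.24, 0.93 to 1.54), and for miR-6236-5p 262 and 147 (log2 1.01, 0.70 to 1.30). Per reads of 15 to 17 nt the log2 ratios were 0.46 for miR-5126-3p (0.12 to 0.79), 0.34 for miR-6538-5p (0.03 to 0.63) and 0.10 for miR-6236-5p (-0.20 to 0.40). The mean GC content of the reads was 100.0% for miR-5126-3p and 93.7% for miR-6538-5p, against 51.2% for miR-6236-5p. Sequences outside miRNA hairpins with 90 to 100% GC had a median log2 ratio of 0.39 per reads of 15 to 17 nt, and a correction for GC content took miR-5126-3p to 0.69, miR-6538-5p to 0.57 and miR-6236-5p just under 2-fold, so none of the 3 kept its place past 2-fold. In the GRCm38 annotation Mir5126 lies on chromosome 1 at 84695839 to 84695915 (plus strand) and Mir6236 on chromosome 9 at 110281287 to 110281409 (plus strand), neither within a gene on its strand. Mir6538, at 26414901 to 26415010 on the minus strand of chromosome 12, lies in an intron of Rnf144a. These are the places of the hairpins. Whether the reads came from them, or from ribosomal RNA left out of the matching, was not tested.

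Below these, miR-340-5p had a log2 ratio of 0.80 (0.26 to 1.31). Also higher were miR-27a-3p and miR-27b-3p, which share nearly all of their reads and cannot be separated here (log2 0.57, 0.36 to 0.77, and 0.56, 0.35 to 0.77), and both arms of miR-6240 (0.55 for miR-6240-5p and 0.52 for miR-6240-3p). The commonest start held 64.1% of the reads of miR-6240-5p and 96.9% of those of miR-6240-3p. Whether fragments of another RNA with the same sequence are among them was not tested. Some ribosomal RNA sequences were left out of the matching, so the reads of both arms cannot be assigned to the hairpin alone. The other members of the highest 10, miR-376a-3p (0.59, -0.11 to 1.23) and miR-191-5p (0.52, -0.01 to 1.02), had intervals that included 0. With all reads in the file as the total, each arm of this paragraph had a log2 ratio below 0.

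The arms at least 2-fold lower in the SB431542 library were miR-181d-5p and miR-341-3p. For miR-181d-5p there were 79 reads with DMSO and 7 with SB431542, 2.97-fold lower (log2 -1.57, -3.02 to -0.55). For miR-341-3p, an arm of the imprinted Dlk1-Dio3 cluster, 654 and 91 reads gave a 2.00-fold lower level (log2 -1.002, -1.34 to -0.69). The neighbour of miR-181d in the genome, miR-181c, was lower too: miR-181c-3p had 235 and 34 reads (log2 -0.93, -1.52 to -0.43). Both hairpins lie on the minus strand of chromosome 8 in an intron of Nanos3, Mir181d at 84178716 to 84178787 and Mir181c at 84178873 to 84178961 (GRCm38). Mir341 lies on chromosome 12 at 109611500 to 109611595, in an intron of the noncoding gene Rian. Also lower were miR-148a-3p (log2 -0.85, -1.26 to -0.48), miR-291a-5p of the miR-290-295 cluster (-0.63, -1.18 to -0.10), miR-152-3p (-0.55, -1.17 to -0.02) and miR-185-3p (-0.44, -0.92 to -0.00074). The remaining members of the lowest 10, miR-434-5p (-0.46), miR-433-3p (-0.40) and miR-182-3p (-0.37), had intervals that included 0.

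**Figure D2:**
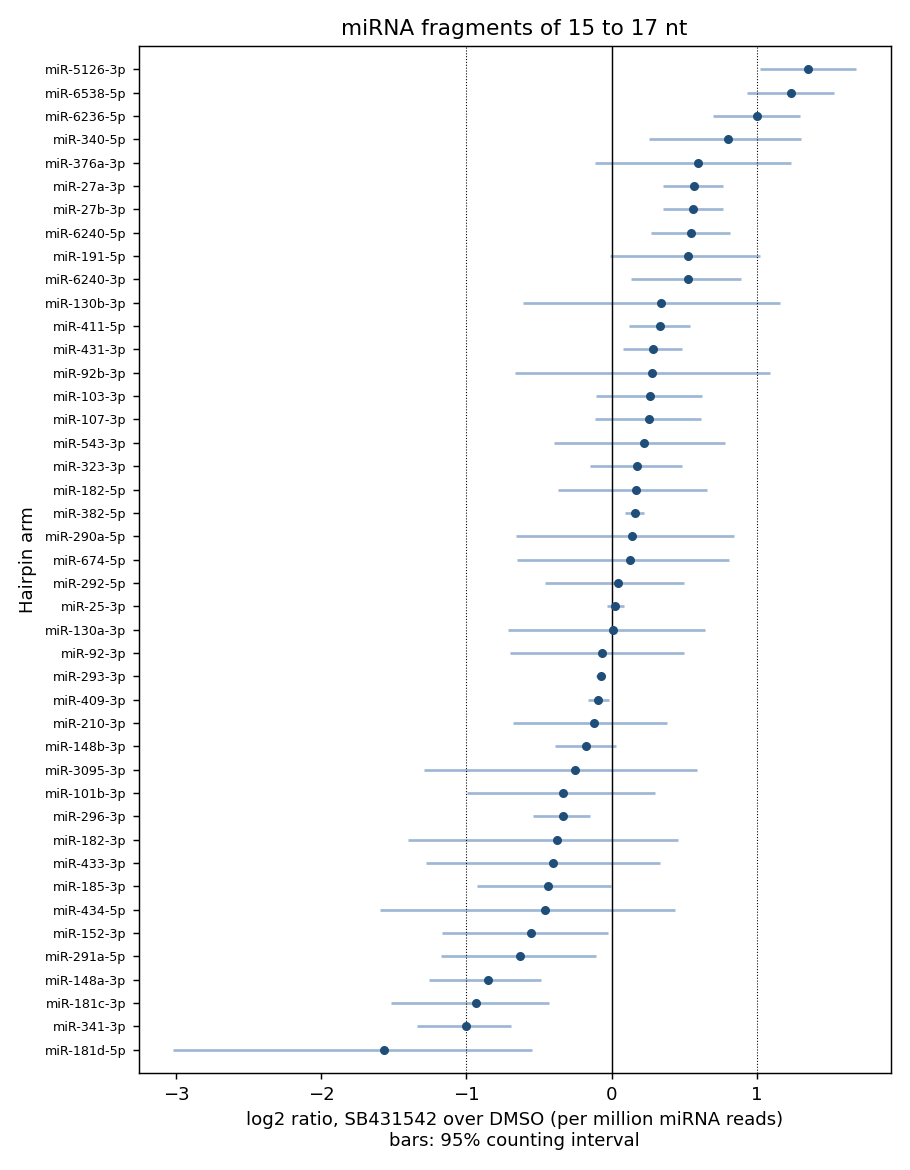
Log2 ratio of SB431542 to DMSO on the RPM scale (horizontal axis) for the 43 hairpin arms with at least 50 reads (vertical axis). Points are the ratios, bars the 95% counting intervals from 1 library per group, and dotted lines mark 2-fold, which miR-5126-3p, miR-6538-5p and miR-6236-5p exceed upward and miR-181d-5p and miR-341-3p downward.

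The split of arms past 2-fold depended on the scale. With edgeR TMM factors or DESeq2 size factors, which move the median log2 ratio by -0.35 and -0.25, 1 arm was at least 2-fold higher and 4 were lower, and with all reads in the file as the total, a shift of -0.96, the numbers were 0 and 18. The edgeR and DESeq2 factors were computed from the arms with a read and not only the 43 described, so arms of few reads enter them. The counting interval lay above 0 for 11 of the 43 arms, below 0 for 10 and included 0 for 22. Arms that share nearly all of their reads, such as miR-27a-3p and miR-27b-3p among the 11, were counted separately. Per reads of 15 to 17 nt it lay above 0 for 2 arms and below 0 for 35, and 40 of the 43 arms had a lower value with SB431542.

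By cluster and family, the third comparison used 18 miRNA lists fixed in advance. The miR-290-295 cluster, the main miRNA cluster of mouse embryonic stem cells, had 4 described arms, none of them 2-fold apart. Its summed reads gave a log2 ratio of -0.07 (-0.10 to -0.04), mostly miR-293-3p, while the other members named, miR-291a-5p and miR-292-5p (0.04, -0.46 to 0.50), had far fewer reads. Its ratio moved with the scale, as that of each list did, to -0.42 with edgeR factors, -0.33 with DESeq2 factors and -1.03 with all reads as the total. The miR-17-92 clusters and their paralogues, linked to proliferation, stood at 0.03 (-0.03 to 0.09), again mostly from a single arm, miR-25-3p, whose hairpin lies within Mcm7 on chromosome 5, while miR-92-3p stood at -0.06 (-0.70 to 0.50). With either edgeR or DESeq2 factors the sign of that list was the opposite. No read of the cluster of miR-302 and miR-367, typical of primed pluripotent cells, was found in either library, which allows up to 38.5 RPM with DMSO and 138 with SB431542.

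The imprinted Dlk1-Dio3 cluster on chromosome 12 had 10 described arms, 1 of them at least 2-fold lower (miR-341-3p) and 9 between. Its summed reads gave a log2 ratio of 0.05 (0.00 to 0.09), which was below 0 with edgeR, DESeq2 and all-read scaling. Within it miR-431-3p (0.28, 0.08 to 0.49) and miR-411-5p (0.34, 0.12 to 0.54) were higher with SB431542 in RPM, but not with edgeR factors or all reads as the total, while miR-382-5p, miR-409-3p and miR-341-3p had the values above. The families of miR-130, miR-301, miR-148 and miR-152 had 5 described arms, none 2-fold apart, and summed reads of 1693 with DMSO and 376 with SB431542 (log2 -0.33, -0.50 to -0.17), lower under each setting run. Their members miR-148a-3p and miR-152-3p were lower, with miR-148b-3p at -0.17 (-0.39 to 0.03).

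Of the miRNAs described in other cells as regulated by TGF-beta and Smad signalling, 3 arms were described: miR-181d-5p, miR-181c-3p and miR-27a-3p. Their median log2 ratio of -0.93 lay at percentile 1.51 among 10000 random lists of the same size matched on mean expression. That percentile rests largely on a single locus, since the neighbouring miR-181c and miR-181d supply 2 of the 3 arms and random lists treat members as independent. By contrast the summed reads, mostly miR-27a-3p, had the opposite sign (log2 0.14, -0.04 to 0.32). That sum was below 0 with edgeR factors (-0.20), DESeq2 factors (-0.11), all reads as the total (-0.81), the total without the 5 most abundant arms (-0.029) and without arms that share reads (-1.05), and with no read minimum the median was 0.25. The percentile of the median was 39.9 for the miR-290-295 cluster, 66.3 for the Dlk1-Dio3 cluster and 22.2 for the families of miR-130, miR-301, miR-148 and miR-152.

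The miRNAs of fibroblasts and feeder cells summed to 314 reads with DMSO and 62 with SB431542 (log2 -0.49, -0.92 to -0.11), and the described member, miR-152-3p, also belongs to the miR-148 and miR-152 families. Those of blood cells had 7 and 2 reads. The miR-183-96-182 cluster had 207 and 63 reads (log2 0.13, -0.31 to 0.53), with miR-182-5p at 0.17 (-0.37 to 0.65). Few reads came from the let-7 family, which accumulates on differentiation (38 and 14), the neural miRNAs (84 and 15), the miR-15/16 family (71 and 15), the Sfmbt2 intron cluster (48 and 17), the Drosha-independent miRNAs (37 and 14), the p53-linked miR-34 family (22 and 9), the endoderm and epithelial miRNAs (12 and 4), the miR-200 family (3 and 1) and the mesoderm and muscle miRNAs (0 and 3). For the last of these both libraries were at or under the floor of 3 reads, and for the others the interval of the log2 ratio in RPM included 0, so no difference was detectable on that scale at this depth. The ratios moved with the scale. The neural list went from -0.61 to -0.96 with edgeR factors, -0.86 with DESeq2 factors and -1.57 with all reads as the total. With all reads the miR-15/16 family stood at -1.32. No interval is given on those scales.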

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

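The tests of the miRNA share and those of GC content in single arms were chosen after the results were seen; the tests of start positions were written before them. Several read classes outside the comparison of miRNA arms were above their DMSO level in the SB431542 library. Reads under 15 nt made up 19.9% of the library against 16.8% with DMSO. Reads of 15 to 17 nt with no match made up 74.1% against 70.3%. Matches to other transcripts made up 8.17% against 6.25%, but antisense matches of that kind were 11.6% and 12.8%, so these read shares cannot be read as messenger RNA. The antisense shares also count reads given to another class by their sense match. Among distinct sequences, without thinning, sense matches were 25.5% with SB431542 and 22.2% with DMSO, and antisense ones 9.34% and 9.10%. Small RNAs outside the main classes made up 0.721% against 0.501%, and sequences found in more than 5 genes 1.09% against 0.732%, but antisense matches of the latter kind were 1.16% and 0.793%, above the sense ones.

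The smaller share of miRNA fragments in the SB431542 library (log2 -0.90, -0.92 to -0.88) was weighed first. The values argue against GC content and length as its whole cause: the leading sequences of the described arms had a median log2 ratio of -0.85, at percentile 0 of 10000 sets of other sequences matched on both. The middle 95% of the medians of those sets ran from -0.56 to 0.04. The sets had a median of -0.27, so GC content and length may account for part of the smaller share. Dilution by sequences without a match would lower all matched classes alike, yet miRNA reads per 100 ribosomal, snoRNA, scaRNA and snRNA reads were 54.9 with DMSO and 36.0 with SB431542 (log2 -0.61, -0.63 to -0.59). That argues against dilution as the whole cause. The shares of those other classes were lower with SB431542 as well, and that of other transcripts higher, so a part played by dilution stays open. Library preparation and the treatment itself cannot be told apart, because each group has 1 library, and a different yield of short fragments from the same miRNAs is open too.

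The arms at least 2-fold higher with SB431542 were weighed next. For miR-6236-5p, whose log2 ratio per reads of 15 to 17 nt was 0.10 (-0.20 to 0.40), so that its RPM value rests on the smaller miRNA total, the GC correction moved the RPM ratio from 1.01 (0.70 to 1.30) to 1.00 (0.70 to 1.29). That value is just under 2-fold, because it began at the threshold, and the small shift argues against GC content as its whole cause. For miR-5126-3p and miR-6538-5p, whose reads are nearly all G and C, it gave 0.69 (0.35 to 1.02) and 0.57 (0.26 to 0.86), so GC content may account for part of the RPM difference and cannot be told apart from the treatment. Per reads of 15 to 17 nt their log2 ratios were 0.46 and 0.34, near the median of 0.39 for other sequences of 90 to 100% GC. What remained in RPM after the correction thus rests on the smaller miRNA total. Fragments of another RNA with the same sequence stay open for the 3 arms, as the median share of reads at the commonest start was 61.1%, between the 50% and 80% set as bounds. By arm the share was 61.1% for miR-5126-3p and 69.4% for miR-6236-5p. For miR-6538-5p it was 46.7%, under the lower bound and on the side set for fragments of another RNA. Some ribosomal RNA sequences were left out of the matching. Fragments of these that hold the same sequence would have been counted in the 3 arms and not set aside.

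The arms at least 2-fold lower were weighed last. For miR-341-3p the corrected log2 ratio was -1.27 (-1.61 to -0.96), against GC content as the whole cause. For miR-181d-5p it was also -1.27, but 7 reads with SB431542 leave an interval of -2.72 to -0.25, so GC content and the treatment cannot be told apart. The median share of reads at the commonest start of these arms, 96.0%, argues against fragments of another RNA cut at many places. Library preparation was not separable from SB431542 here either.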

How the results depend on the processing

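The length, set-aside and GC settings, the thinned distinct sequences and the share without abundant arms were chosen after seeing the data. Against 3 arms at least 2-fold higher and 2 lower, edgeR TMM and DESeq2 factors each gave 1 higher and 4 lower, the total of all reads 0 and 18, no minimum 95 and 27 of 329 arms, no sequence set aside 5 and 3, and the GC correction 1 (miR-340-5p) and 2. Without the 5 most abundant arms in the total the counts were 2 and 4, with a pseudocount of 5 reads 3 and 0, with the DMSO library thinned or sequences of at least 14 nt 2 and 1, and with a minimum of 200 reads or sequences of at least 16 nt 3 and 1. Setting no sequence aside brought in miR-3473b-3p (log2 1.41), miR-3473e-5p (1.42) and miR-1946a-3p (1.45) and took miR-6236-5p below 2-fold; these arms were named after their values were seen. With sequences of at least 17 nt neither lower arm remained, and miR-148a-3p and miR-181c-3p took their place. The miRNA shares with DMSO and SB431542, 7.87% and 4.21%, were 7.47% and 3.91% from 14 nt, 6.61% and 3.61% from 16 nt, 4.08% and 2.30% from 17 nt, 8.12% and 4.58% with no sequence set aside and 1.36% and 0.771% without the 4 most abundant arms, lower with SB431542 in each. By distinct sequences they were 1.15% and 1.18%, and 1.37% and 1.18% with the DMSO library thinned, so the former direction goes with the unequal depth. The Dlk1-Dio3 sum turned from 0.05 to -0.30 with edgeR, -0.21 with DESeq2, -0.91 with all reads, -0.13 without the 5 most abundant arms, -0.021 from 17 nt and -0.030 with no sequence set aside. Of the 223 list sums recomputed, 187 stayed within the main counting interval, as did 358 of 431 ratios of named arms. Under 1 setting or more, 16 of the 31 described named arms turned sign, 9 of them not only with all reads as the total, among them miR-292-5p (8 settings), miR-25-3p (7), miR-182-5p (6) and miR-382-5p (4); none of the 5 past 2-fold did. Of 16 list sums 11 turned, 6 of them not only with all reads, among them the miR-17-92 clusters (7 settings), the TGF-beta list (5), the miR-183-96-182 cluster (4) and the blood cell list (4). Apart from changes of the total, of the minimum or of the reads counted, the cause was not tested. Assignment by equality with mature sequences was not run, as no mature sequences were used here, nor were shares of 18 to 26 nt reads, as all reads analysed were shorter. No paired analysis was possible because each group has 1 library. Depth limits lists under 100 reads and arms such as miR-181d-5p, with 7 reads in the SB431542 library.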

Other observations

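Fragments of other structured RNAs went both ways between the libraries per 1000000 reads of 15 to 17 nt, the scale used for them. Snord83b, the most abundant snoRNA here, was lower with SB431542, at 2191 against 2757 (log2 -0.33, -0.43 to -0.23). Snord14c and Snord14d, which guide ribosomal RNA methylation and share their reads, had 194 and 42 reads each (log2 -1.27 and -1.26, both with an interval of -1.79 to -0.78). Fragments of the mitochondrial ribosomal RNAs were lower as well, mt-Rnr2 at -0.63 (-0.98 to -0.30) and mt-Rnr1 at -0.50 (-0.91 to -0.12), and those of 5S ribosomal RNA at -0.14 (-0.19 to -0.10). In the other direction, Gm22514, the most abundant of the other small RNAs, stood at 0.59 (0.49 to 0.68) and Gm26917, counted here as ribosomal RNA, at 0.33 (0.20 to 0.46), while Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle that share reads, were higher at 0.35 (0.15 to 0.56). The mitochondrial tRNA genes went both ways, with mt-Tp at -0.89 (-1.61 to -0.26) and mt-Tc at 0.71 (0.12 to 1.30). These genes were named after their values were seen.

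Sequences outside miRNA hairpins had higher ratios at higher GC content from 30% upward, the median log2 ratio being -0.72 at 30 to 40% GC (249 sequences), -0.22 at 50 to 60% (1106 sequences) and 0.39 at 90 to 100% (176 sequences). Below 30% GC the median was -0.52 (99 sequences). Among 832 such sequences with at least 200 reads, 14.5% were 2-fold or more apart between the libraries per reads of 15 to 17 nt (SD of the log2 ratio 0.71, median -0.02), and among 33 miRNA hairpin sequences with as many reads 39.4% were (SD 0.42, median -0.89). Fragments of most described arms began at a single position: the median share of reads at the commonest start was 96.9%, and 33 of the 43 arms had at least 80% there. Among the exceptions were miR-409-3p (61.9%), miR-411-5p (55.7%) and miR-6538-5p (46.7%).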
